A study of Drosophila melanogaster with 2 samples.

How the data were processed

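ChIP-seq of eGFP-tagged CG11398 in whole embryos gave 2 samples in 1 group, biological replicates 1 and 3 per the labels. Chromatin was sheared by sonication, with a size range of 200 to 800 given per the labels. Reads were processed by the authors into peak lists, which are what was analysed here. Per the notes deposited with the files, each replicate's relaxed list was derived from its alignments and a control, and the pooled and thresholded lists from both replicates. The thresholded list is the optimal set by the irreproducible discovery rate (IDR), per the same notes. The aligner, the peak caller, their versions and their thresholds are not given in the sources used here. The control was not used here.

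Each list has a signal value per region as deposited by the authors, with no stated normalization, and it was used to rank and describe regions within a list. Between lists it was compared as deposited, without normalization, as in the log2 ratio of the replicate signals. The deposited -log10 of the q-value ran from 3.01 to 3.60 in the thresholded dm6 list, where 1997 peaks (73.6%) shared the highest value, so it was not used to rank them. The summit position was taken from the deposited offset. Lists were given in 2 builds, dm3 and dm6. Read depth is unknown, because the lists carry no read counts. Regions are not replicates: the tests over regions describe how regions are sorted in these lists, and the binomial and Poisson intervals cover counting error only.

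The dm6 lists were analysed with the Release 6 genome sequence and the Ensembl release 115 annotation. All dm6 regions ended within the reference arms, and 17681 of 17683 genes present in both the Ensembl and RefSeq annotations had identical positions. Of the annotation, 18164 genes on 6 main arms were used, without transposons. No dm3 genome was used here, so dm3 lists served only for counts, overlaps and signal.

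Overlap meant at least 1 bp shared. It was computed in Python and checked with bedtools 2.31.1, which gave the same 17958 regions. Chance overlap came from 100 random placements on the same arms, and for top regions from 100 shuffles of ranks. Ranks were shuffled over all regions of each list, although the plan had named the shared regions. A summit was at a promoter within 500 bp of an annotated TSS, and remaining summits were classed in the order 5' UTR, 3' UTR, coding sequence, non-coding exon, intron and intergenic. The background for peaks was the 26648 pooled relaxed regions that overlapped no thresholded peak. Gene lists were tested among 8635 genes with a pooled relaxed summit within 500 bp of a TSS, if at least 5 members were testable. A promoter shared by neighbouring genes counts for each of them, and for small RNAs the TSS is the annotated start. Consensus sites and all 7-mers, merged with their reverse complements, were searched on both strands within 50 bp of the summit. All tests were Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05.

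The 28 gene lists, 21 consensus sites, tests and alternatives were fixed before the data were examined, apart from the departures that are stated. Later, 5 list symbols were replaced by the names the annotation uses. The lists were cytoplasmic and mitochondrial ribosomal proteins, histones, tRNAs, small nuclear and nucleolar RNAs, proteasome, translation factors, respiratory chain, chemoreceptors, cuticle, eggshell and yolk, Hox, maternal and gap, pair-rule, segment polarity, Notch, neurogenesis, mesoderm, dorsoventral, Polycomb, trithorax, insulator, cell cycle, heat shock, nuclear receptors, clock, EGFR and JAK-STAT, and trachea. Genes were named by a rule fixed at the same time: CG11398, the nearest genes of the 25 strongest peaks (ties within 50 bp), up to 4 members per list with the strongest promoter peak, the 10 enriched 7-mers of smallest p, and every member of a count of 5 or fewer.

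Alternatives were 50% reciprocal overlap, summits within 100 bp, promoter windows of 200 and 1000 bp, summit windows of 100 bp, flanks of 5 and 50 kb at CG11398, the stronger 50% of peaks, the dm3 lists, other backgrounds, and each replicate left out. Leaving out a replicate meant taking the 2712 top regions of the other one. Matched regions had the same promoter status and GC content in bins of 2 percentage points over the 100 bp on either side of the summit, at most 3 per peak. The flanks 300 to 400 bp from a summit were first joined into 1 sequence longer than the summit window. This error was found from its results, and each flank was then counted as a sequence of its own, as long as the window. A random background of 7915 relaxed regions was added after seeing the data.

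The tests were run on simulated data. With no word planted, 5 random draws of relaxed regions as peaks each gave 0 calls among 8192 7-mers, and a word planted in 2%, 5% or 10% of the sequences was recovered each time. The draws had the base composition of the background, whereas the real peaks were poorer in GC. They do not show how many calls such a difference alone would give. For the comparison of gene lists, among 8635 genes with a peak share of 20%, a list of 29 genes raised to 60% was called in 95 of 100 draws, and 4 of 100 draws without a raised list gave any call. Raised lists of other sizes were not simulated. Each gene was given a peak independently in these draws, whereas neighbouring genes in the data can share a peak. The draws therefore do not give the rate of false calls for lists of clustered genes, which the exact test also treats as independent. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.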

Results

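Chromatin immunoprecipitation and sequencing (ChIP-seq) was used to map the product of CG11398, an X-linked Drosophila melanogaster gene, on chromatin of whole embryos. The embryos were collected over 0 to 24 h of development, were of mixed sex, and carried CG11398 fused at its C terminus to eGFP, which was pulled down with an antibody to GFP. The data formed 1 group of 2 biological replicates, numbered 1 and 3. Each replicate had its own list of 30000 relaxed regions, in which weak background regions are kept on purpose. A further relaxed list of 30000 regions came from the pooled replicates, and a thresholded list held 2712 peaks in the dm6 genome build. Signal values in the thresholded list ran from 79.8 to 1410, with a median of 115.1. The median peak was 416 bp wide and the widest 436 bp. In the relaxed lists of replicates 1 and 3 the median width equalled the maximum, at 424 bp and 396 bp, so many regions shared a single width. With a single group, the comparisons were between the replicates, and between thresholded peaks and the relaxed regions that overlapped none of them. No control or expression data were analysed here, so binding was not told apart from signal at open or highly transcribed promoters.

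The first question was whether both replicates marked the same places. The peaks at cbt, px, CG14100 and Ugalt, the 4 strongest of the pooled list, ranked between 1 and 5 in each replicate. Of the 25 strongest peaks, 23 were among the top 25 regions of replicate 1 and 24 among those of replicate 3. For 134 thresholded peaks the log2 ratio of the replicate signals lay beyond 2 SD of its median, among them a peak at bnl, which encodes a fibroblast growth factor (70.2 in replicate 1 and 14.9 in replicate 3). The cut was set by the spread of the ratio itself, so some peaks fall beyond it in almost any list. The count is therefore no measure of disagreement between the replicates. Each of the 2712 thresholded peaks overlapped a relaxed region in both replicates. The ranks of the strongest peaks and this overlap were largely fixed by selecting the peaks on both replicates together, so they are no separate evidence, unlike the comparison of the replicate lists that follows. Over all relaxed regions, 17958 of 30000 in replicate 1 (59.9%, exact 95% interval 59.3 to 60.4) overlapped one in replicate 3, while 100 random placements gave 16.7% on average and at most 17.3%. Among the 2712 top regions of replicate 1, 1909 (70.4%) overlapped a top region of replicate 3, against 6.40% when ranks were shuffled over each whole list. The planned shuffle within the shared regions was not run. Spearman's rho of the signal across regions was 0.520 over the 17958 shared regions and 0.626 over the thresholded peaks, and regions are not independent replicates. The value over the thresholded peaks comes from peaks selected on both replicates together, so it is no separate evidence either. When summits had to lie within 100 bp of each other, the share of replicate 1 regions found again was 36.2%.

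The 25 strongest peaks were assigned to the gene with the nearest transcription start site (TSS), which named 26 genes. The strongest peak (signal 1410, 2L 480866 to 481301 in dm6) had its summit at -1399 bp from the TSS of cbt, which encodes a zinc-finger transcription factor, inside an intron of ush. The next were at px (1326, summit at -184 bp), a gene named for its wing vein phenotype, CG14100 (1239, -85 bp) and Ugalt (1234, -27 bp), which encodes a UDP-galactose transporter. Further down the 25 were ph-p of the Polycomb group at 952.7 (X 2137188 to 2137545) and Chro, which encodes the chromosomal protein Chromator, at 875 (3L 22878734 to 22879079). A single peak of signal 813 stood between Art3, a gene for an arginine methyltransferase, and mRpS10, a mitochondrial ribosomal protein gene, with its summit at -114 bp and -143 bp from their TSSs. mRpL41 (834, or 419 in replicate 1 and 418 in replicate 3) and PNPase (960.0), which encodes the mitochondrial polynucleotide phosphorylase, also carried promoter peaks. The others were Lk6, CG11050, CG1888, CG13323, cno, CenG1A, gish, CG9663, Sox14, CG31145, larp, CG32772, CycB and the non-coding genes lncRNA:CR31840, lncRNA:CR44619 and lncRNA:CR45643, with signals from 615 to 1110. Of the 25 summits, 16 were at promoters, 6 in introns and 3 between genes, and the summit assigned to CG13323 lay 11892 bp from its TSS.

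Promoters held most of the thresholded peaks, and coding sequence held almost none. In all, 1468 of 2712 summits (54.1%, exact 95% interval 52.2 to 56.0) were within 500 bp of an annotated TSS, compared with 30.0% of the 26648 other relaxed regions (odds ratio 2.75, Fisher's exact test, two-sided, adjusted p = 2.695e-134). Outside promoters, 8 summits (0.295%) were in coding sequence, compared with 16.5% of the other relaxed regions (odds ratio 0.0149, exact test, adjusted p = 1.692e-184) and 13.3% of random positions. The 3' UTRs held 0.664% of summits against 3.06% (exact test, adjusted p = 1.664e-16), and intergenic sequence 11.0% against 14.3% (adjusted p = 2.044e-06). Introns held 32.3% against 34.0% and did not pass the test (exact test, adjusted p = 0.0859), nor did 5' UTRs (adjusted p = 0.0677). Near a TSS, the peaks sat upstream: their median summit was at -61 bp and 69.7% were upstream, whereas the other relaxed regions had a median of 27 bp and 44.2% upstream (odds ratio 2.90, Fisher's exact test, p = 3.849e-73). This comparison of sides was not among the tests fixed beforehand, and its p was not adjusted. From the weakest to the strongest quartile of signal the promoter share was 53.7%, 53.5%, 52.1% and 57.2%, with overlapping exact 95% intervals (49.9 to 57.5 in the weakest and 53.4 to 61.0 in the strongest). Against random positions, the odds ratio for promoters was 7.59.

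**Figure D1:**
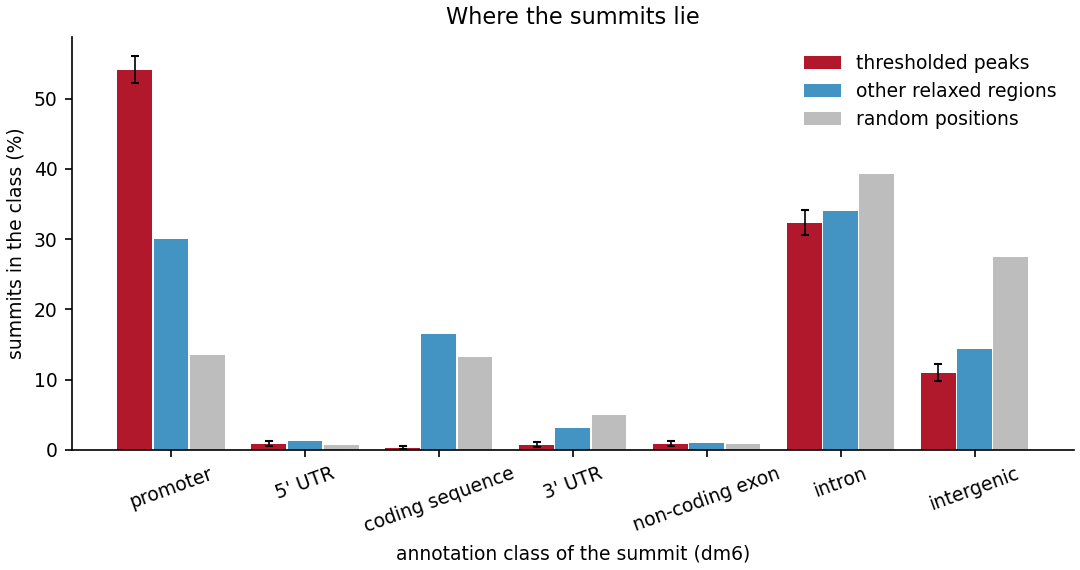
Share of summits in each annotation class, in percent, for the 2712 thresholded peaks (bars with exact 95% binomial intervals), the 26648 other relaxed regions and 27120 random positions. Promoters took 54.1% of the thresholded summits and coding sequence outside promoters 0.295%.

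No chromosome arm passed the test of its share of peaks against the other relaxed regions. The X chromosome had 468 peaks (17.3% against 16.1% of other relaxed regions, odds ratio 1.09, Fisher's exact test, adjusted p = 0.383), and chromosome 4 had 11 (0.406% against 0.660%, adjusted p = 0.383). Chromosome 4 carried 8.16 peaks per Mb and the other arms between 19.6 and 21.8. With the top regions of replicate 3 in place of the thresholded list, X had an odds ratio of 1.16 and passed the test (exact test, adjusted p = 0.0310), as did chromosome 4 with 0.437 (adjusted p = 0.0466).

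Genes for cytoplasmic ribosomal proteins carried peaks at their promoters far more often than other genes. Of 78 such genes with a relaxed region near a TSS, 60 had a thresholded peak (76.9%, exact 95% interval 66.0 to 85.7), each a distinct peak, compared with 21.7% of the other genes (odds ratio 12, Fisher's exact test, adjusted p = 2.359e-23). The strongest were at RpS27 (signal 539.6), RpL7 (491), RpL14 (443) and RpL23A (374), with summits between -102 bp and 38 bp from the TSS. At RpS27 the signal was 277 in replicate 1 and 260.1 in replicate 3. The tRNA genes stood on the other side: 11 of 148 (7.43%) had a peak within 500 bp of the annotated start, compared with 22.5% of the other genes (odds ratio 0.277, exact test, adjusted p = 2.503e-05). These 11 genes held 10 distinct peaks. The strongest were near tRNA:Tyr-GTA-1-8 (358), tRNA:Val-CAC-2-5 (202), tRNA:Trp-CCA-2-2 (160) and tRNA:Phe-GAA-1-2 (151). The peak near tRNA:Phe-GAA-1-2 was that of RpL17, with its summit at -51 bp from the TSS of RpL17 and 254 bp from the tRNA start. The ribosomal protein and tRNA lists were the 2 of 26 tested lists that passed, and 3 had an unadjusted p under 0.05. tRNA genes are repeated, and 148 of 295 could be tested.

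The next 5 lists did not pass the test. Mitochondrial ribosomal protein genes had a peak in 17 of 54 cases (31.5%, exact test, adjusted p = 0.381), led by mRpL41, mRpS10 (813), mRpS23 (763) and mRpL23 (352). The peak of mRpS23 was that of CenG1A, at -387 bp from the TSS of mRpS23 and -105 bp from that of CenG1A. Translation factors had 11 of 35 (31.4%, exact test, adjusted p = 0.475), among them eIF6 (565), eEF1gamma (389), eIF1 (279) and eIF3h (207). The peak of eIF1 was that of RpL28, at -326 bp from the TSS of eIF1 and -55 bp from that of RpL28. Proteasome subunits had 6 of 29, led by Rpn5 (168), Rpt5, Rpn3 and Prosbeta1, and the respiratory chain and ATP synthase 10 of 57, led by ND-ASHI (178), ND-MWFE, ND-51 and ATPsynC. Small nuclear and nucleolar RNA genes had 20 of 119 on 17 distinct peaks, led by snoRNA:U49:66Da, snoRNA:Or-CD11a, snoRNA:Psi28S-2949 and snoRNA:Or-aca5. The peak of snoRNA:U49:66Da was that of RpL14, and the peak of snoRNA:Or-CD11a was that of RpL28. More snoRNA genes shared a peak with RpS12, RpL17, RpS29 and RpL10Ab. Distances were taken from the annotated start, so peaks near snoRNA genes need not be at promoters of their own. The list of small nuclear and nucleolar RNAs joined opposite classes, as a test by gene class looked at after the data were seen had snRNA genes with more peaks (7 of 14, odds ratio 3.51, Fisher's exact test, adjusted p = 0.0247) and snoRNA genes with fewer (13 of 105, 0.491, adjusted p = 0.0193). The snRNA call rests on few genes: 2 of the 7, snRNA:U6:96Ab and snRNA:U6:96Ac, shared a peak, and as a family by symbol they did not pass (6 of 13, exact test, adjusted p = 0.220). In the stronger 50% of the peaks, translation factors passed the test with an odds ratio of 3.46 (Fisher's exact test, adjusted p = 0.0215). The peak shared by eIF1 and RpL28 counted there.

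Among genes of chromatin proteins and signalling, 5 of 11 Polycomb group genes had a peak (ph-p, Psc, Sfmbt, Su(z)12 and Scm), as did 4 of 10 insulator genes (Chro, Dref, Cp190 and CTCF) and 2 of 9 trithorax group genes (Trl and brm). The peak of Dref was also that of RpL13, at -60 bp from the TSS of Dref and -24 bp from that of RpL13. Nuclear receptor and ecdysone response genes had 7 of 18, led by Eip75B (329), Hr96, usp and Hnf4. EGFR and JAK-STAT genes had 7 of 16, led by spi (337), which encodes the EGFR ligand Spitz, Stat92E, Socs36E and rho. The heat shock list had 5 of 14, at Hsp83 (348), Hsp26, Hsp27, lncRNA:Hsromega and Hsc70-5, and the clock list 2 of 8, at sgg (318) and dco. None of these 7 lists passed the test (adjusted p from 0.381 to 1), and 3 passed with the wider background given below.

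None of the lists of patterning genes passed the test. None of 8 Hox genes (0%, exact 95% interval 0 to 36.9) and none of 7 pair-rule genes had a peak. Maternal and gap genes had 2 of 11 (nanos and bcd), segment polarity, Wnt and Hedgehog genes 2 of 17 (nkd and smo), and dorsoventral and BMP genes 2 of 16 (ush and rho). Mesoderm and muscle genes had 2 of 17 (sls and htl), tracheal genes 1 of 7 (bnl), and neurogenesis genes 4 of 18 (elav, pros, scrt and brat). The Notch list had 5 of 18 (E(spl)m7-HLH, E(spl)m3-HLH, N, numb and mam), and the cell cycle list 5 of 27 (Dp, dpa, dup, fzr and Mcm5). Among genes of late or narrow expression, 1 of 15 chemoreceptors (Gr63a) and 0 of 16 cuticle protein genes had a peak. The 111 histone genes had no relaxed region near a TSS, so they were not tested against this background, and the eggshell and yolk list had 2 testable genes and no peak.

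The number of lists called depended on the background. With all 18164 annotated genes, 11 of 28 lists passed (6 with more peaks and 5 with fewer). Small nuclear and nucleolar RNAs, with 119 of 306 testable, were among those with fewer (odds ratio 0.587, Fisher's exact test, adjusted p = 0.0490). Those added with more peaks were mitochondrial ribosomal proteins (odds ratio 2.58, Fisher's exact test, adjusted p = 0.00647), EGFR and JAK-STAT genes (5.40, adjusted p = 0.00647), nuclear receptor and ecdysone response genes (3.96, adjusted p = 0.0208), Polycomb group genes (4.24, adjusted p = 0.0490) and translation factors (2.33, adjusted p = 0.0490). This background counts genes without any relaxed region as genes without a peak, which fixed the call of the histone list, so that call is not a result. It also weighs on the calls of fewer peaks at chemoreceptors, with 15 of 185 testable, and cuticle proteins, with 16 of 120. The same counting raised the added calls of more peaks, since those lists were testable more often than the 8635 of 18164 genes. Of EGFR and JAK-STAT genes 16 of 18 were testable, and of mitochondrial ribosomal proteins 54 of 73. Among testable genes the lists added with more peaks did not pass. Their odds ratios were lower there, such as 2.73 for EGFR and JAK-STAT and 1.61 for mitochondrial ribosomal proteins. With the top regions of replicate 3 alone, 4 lists passed, and the added ones had fewer peaks. They were cuticle proteins (odds ratio 0, exact test, adjusted p = 0.00680) and chemoreceptors (odds ratio 0, adjusted p = 0.0269).

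**Figure D2:**
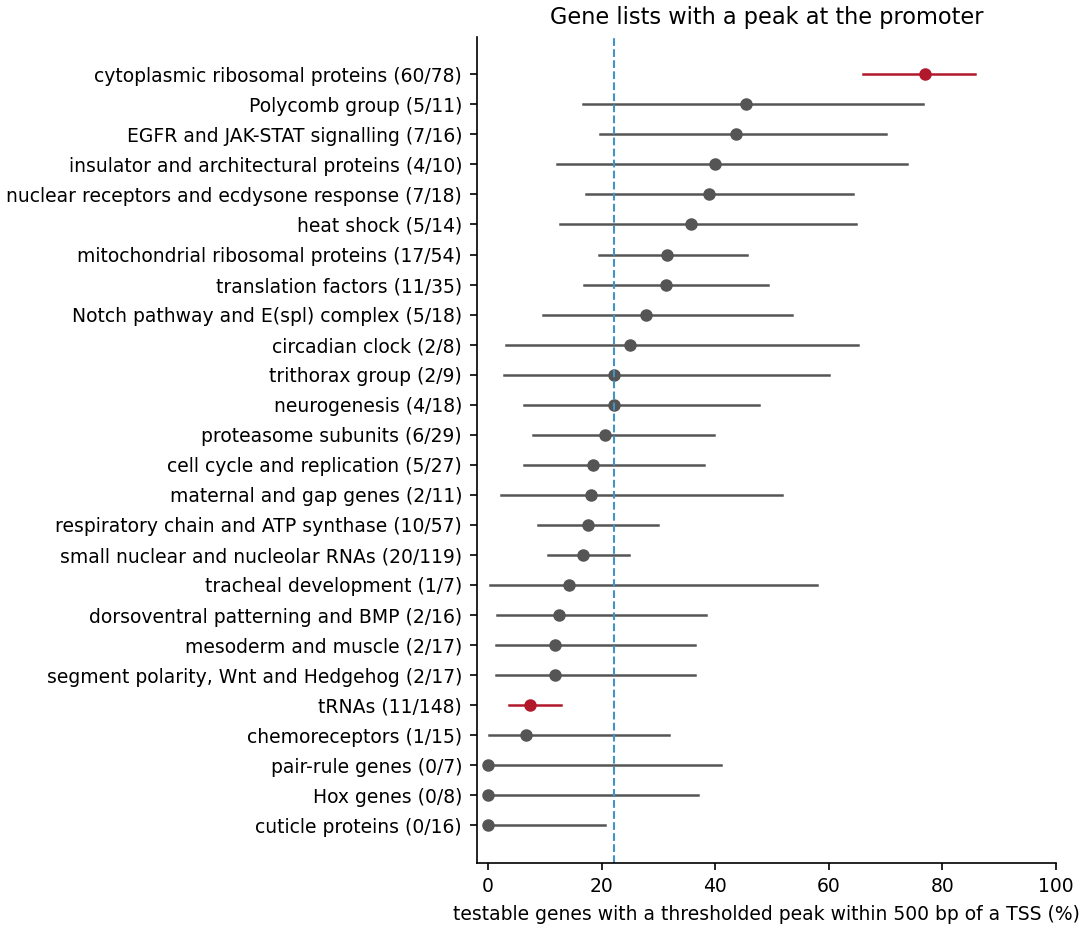
Percent of testable genes with a thresholded peak within 500 bp of a TSS, for each of the 26 tested lists, with exact 95% binomial intervals as lines and the numbers of genes in parentheses. Red marks the 2 lists with an adjusted p under 0.05, and the dashed line marks all testable genes (22.2%).

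Sequences within 50 bp of the summits were compared with known consensus sites. The Forkhead core TGTTTAC was present at 146 peaks (5.38%, exact 95% interval 4.56 to 6.30) and at 2.57% of other relaxed regions (odds ratio 2.16, Fisher's exact test, adjusted p = 6.688e-13). The DNA replication-related element TATCGATA, bound by Dref, was at 2.10% against 0.728% (odds ratio 2.93, exact test, adjusted p = 1.657e-09). The TATA box, CGATA core, homeodomain core TAATTA, GATA core, E-box CATATG and Ohler motif 1 were also more frequent at peaks, with odds ratios from 1.33 to 1.90, and a CACA repeat was less frequent (0.649, exact test, adjusted p = 0.00771). The Zelda site (1.84% against 2.39%, exact test, adjusted p = 0.133), the GAGA repeat (2.397% against 2.0%, adjusted p = 0.229) and the CTCF core (2.21% against 2.62%, adjusted p = 0.280) did not pass here, and all 3 passed under at least 1 other setting given below. The tRNA B box was at 0 of 2712 peaks, which allows a share of up to 0.111% by a limit of 3 counts, or 0.136% by the exact 95% interval.

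Peaks were poorer in GC than the other relaxed regions, with a mean of 39.2% (SD 7.00) over the 100 bp on either side of the summit, against 45.7% (SD 8.98). The main arms as a whole had 42.1%, so peaks lay below the genome and the other relaxed regions above it. Against 7915 relaxed regions matched on GC content and promoter status, the Forkhead core kept an odds ratio of 1.496 (Fisher's exact test, adjusted p = 0.00343), and the other sites that were more frequent at peaks did not pass. The poly-A run AAAAAAAA, a control sequence, was then less frequent at peaks (5.53% against 7.38%, exact test, adjusted p = 0.0103), whereas it was more frequent with 100 bp windows (odds ratio 1.30, adjusted p = 1.065e-04) and without replicate 1 (1.52, adjusted p = 6.760e-06). Other settings also ended calls: the E-box CATATG (odds ratio 1.25), homeodomain core (1.09) and GATA core (1.23) did not pass against the flanks of the same summits, and Ohler motif 1 was at 0.930 in the stronger 50% of peaks. Against those flanks the DNA replication-related element (5.27, exact test, adjusted p = 4.207e-11) and Ohler motif 1 (3.74, adjusted p = 2.471e-04) did pass, as did the Forkhead core (1.93), the CGATA core (1.53) and the TATA box (1.396). With a replicate left out, Ohler motif 1 was at 1.18 without replicate 3 (exact test, adjusted p = 0.744) and CATATG at 1.18 without replicate 1 (adjusted p = 0.222). Against as many random relaxed regions as matched ones, a background chosen after seeing the data, Ohler motif 1 did not pass either (1.73, exact test, adjusted p = 0.0883). The CACA repeat did not pass with either replicate left out (odds ratios 0.724 and 0.938) or with 100 bp windows (0.895), and passed against matched regions (0.639, exact test, adjusted p = 0.0300) and flanks (0.459, adjusted p = 1.630e-06). Settings added calls as well: without replicate 3 the Zelda site was less frequent at peaks (0.697, exact test, adjusted p = 0.0385) and the GAGA repeat more frequent (1.36, adjusted p = 0.0360). With 100 bp windows the GAGA repeat (1.42, exact test, adjusted p = 3.946e-04) and the CTCF core (0.795, adjusted p = 0.0426) passed, while against flanks the GAGA repeat was less frequent (0.662, adjusted p = 0.0138). The E-box CAGCTG was less frequent in the stronger 50% of peaks (0.731, exact test, adjusted p = 0.0427) and without replicate 1 (0.756, adjusted p = 0.00836), and the heat shock element more frequent without replicate 1 (1.38, adjusted p = 0.0147).

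Among all 8192 7-mers, 1028 were more frequent at peaks and 1349 less frequent. The 10 with the smallest p were TTTAAAA, TTAAAAA, AATTTAA, ATTTTAA, AAAAAAT, ATTTAAA, AAAATAT, GTAAATA, TAAAATA and AAATATT. The first of these was at 9.22% of peaks and 4.12% of other relaxed regions (Fisher's exact test, adjusted p = 1.522e-23). Against the matched regions, 9 7-mers were more frequent and 1 less frequent, and of the 10 named above only GTAAATA passed (5.71% against 3.70%, exact test, adjusted p = 0.0198). The others that passed were GCGCAGC, AACCCTG, ACCGGAA, AACACTG, AGTGTTG, GCAAACA, AGCCCTG and ATGTTTA, and CACCTGC was less frequent (0.258% against 1.25%, exact test, adjusted p = 0.00672).

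The tagged gene itself had a peak. CG11398 (FBgn0040366, X 1211989 to 1215156 in dm6, minus strand) carried 1 thresholded peak at X 1214961 to 1215376, with its summit at -13 bp from the TSS. Its signal of 82.5 ranked 2538 of 2712, with 43.6 in replicate 1 (rank 2991) and 32.4 in replicate 3 (rank 3726). No other thresholded peak lay within 20 kb. That window held 16 pooled relaxed regions (95% Poisson interval 9.14 to 25.98), more than in 74.6% of 10000 random windows of the same size. The peak was not among the stronger 50% of peaks, nor among the 2712 top regions of either replicate alone.

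**Figure D3:**
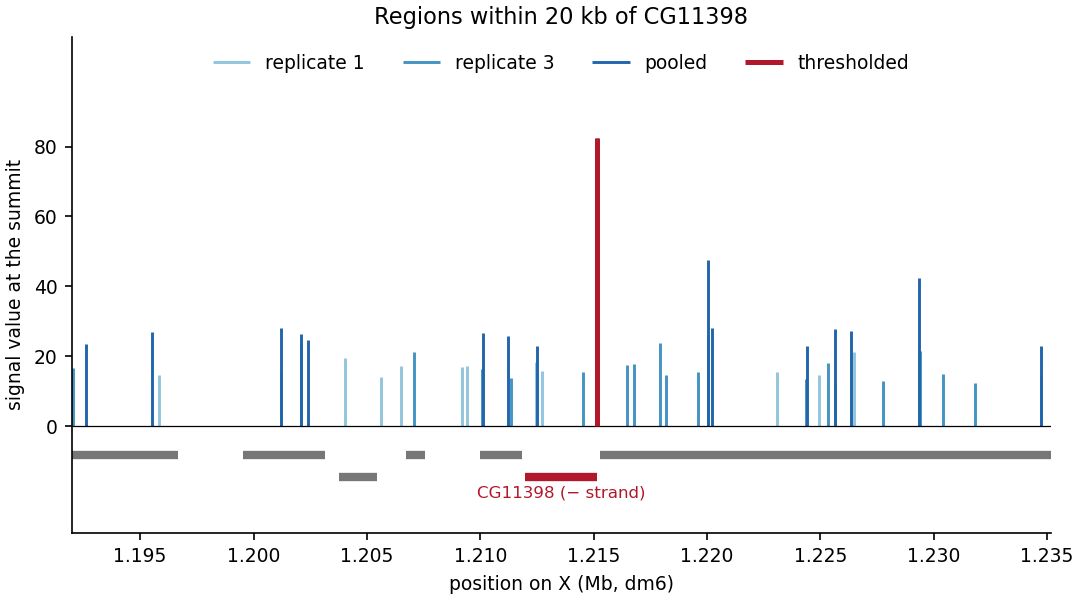
Signal value at each region's summit within 20 kb of CG11398 on X (position in Mb, dm6), for the relaxed lists of replicate 1, replicate 3 and the pool and for the thresholded list. Horizontal bars show annotated genes, with CG11398 in red, and the thresholded peak (signal 82.5) stands at the TSS of CG11398.

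The peak lists in the older build dm3 were close in size and strength to those in dm6. The thresholded dm3 list had 2732 peaks with a median signal of 114.6, and in it X held 466 peaks and chromosome 4 held 11. In both builds the thresholded list consisted of the pooled regions of highest signal. No coordinates were converted between builds.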

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

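The following values came from data outside the main comparisons. Counts per arm in dm3 were set before the data were seen, and no test of sequences outside the 6 main arms was listed with them. The pooled dm3 list held 22 relaxed regions outside the 6 main arms, above the 3 that a count of 0 allows. The strongest had a signal of 103, and 2 of the thresholded dm3 peaks lay there, both on Uextra beside 5 other regions (odds ratio 3.90, Fisher's exact test, adjusted p = 0.754). The other such sequences had no peak and did not pass. The dm6 lists held none.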

How the results depend on the processing

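The comparison with random relaxed regions as numerous as the matched ones was chosen after seeing the data. The flank comparison was set before and corrected after its results were seen, and the others were set before. The promoter share and the depletion from coding sequence kept their direction and passed under every alternative run on them, as did the ribosomal protein and tRNA lists wherever they could be tested (tRNAs fall outside protein-coding genes) and the Forkhead core. Across single lists, motifs, 7-mers and classes, 315 of 403 values kept their direction and side of the threshold, 24 lost the call, 21 gained one and 43 turned. Read depth is unknown, so its effect was not measured. The cause of the changes below was not tested unless stated.

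Replicate overlap fell to 47.8% with 50% reciprocal overlap and 36.2% with summits within 100 bp. The share of top regions was 65.7% with reciprocal overlap and 74.2% with 50% as many regions. Support by each replicate was at least 94.7% with reciprocal overlap and 96.9% by summits. The odds ratio of X ranged from 0.996 to 1.16 with a replicate left out. Lists called numbered 11 with all genes, where the histone list was called only because none of its genes had a relaxed region, 1 with protein-coding genes, where tRNAs drop out by construction, and 2 to 4 with a replicate left out. Motifs called fell from 9 to 3 with matched regions. Called 7-mers fell from 2377 to 669 against flanks, 1362 in the stronger 50% of peaks, where fewer peaks were tested, and 10 with matched regions. The random background of equal size called 1873, so the smaller number of regions alone did not give the drop to 10. Peaks at CG11398 numbered 2 within 50 kb, 0 in the stronger 50%, and 0 with either replicate left out, where its ranks lie beyond 2712.

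Most odds ratios that crossed 1 were of lists and sites not called. The exceptions were Ohler motif 1, called in the report, and GAGA against flanks and the poly-A run against matched regions, which were called there. With all genes they were proteasome 1.21, respiratory chain 1.10, maternal and gap 1.30, segment polarity 1.13, neurogenesis 1.61, trithorax 1.88 and cell cycle 1.69. With a 200 bp promoter they were proteasome 1.02, Notch 0.891, trithorax 1.64 and clock 0.817. With 1000 bp they were small RNAs 1.22, trithorax 1.29 and cell cycle 1.05, and in the stronger 50% of peaks Notch 0.935 and trithorax 2.14. With a replicate left out the ranges were mitochondrial ribosomal proteins 0.987 to 1.44, maternal and gap 0.797 to 1.58, Notch 0.788 to 1.23, neurogenesis 0.981 to 1.53, trithorax 1.60 to 2.21, EGFR and JAK-STAT 0.920 to 3.20, initiator 0.999 to 1.05, Grainyhead 0.533 to 0.574 and tRNA B box 0 to 1.64. Against matched regions, Ohler motif 1 was 0.973, CACGTG 1.05, CTCF 1.41, Grainyhead 0.625 and the poly-A run 0.735. Against flanks, GAGA was 0.662, CAGCTG 1.01, CTCF 1.23 and poly-A 0.904. With 100 bp windows, CACGTG was 1.03, Grainyhead 0.672 and the B box 1.97. In the stronger 50%, Ohler motif 1 was 0.930, CACGTG 1.10 and Grainyhead 0.652, and with the equal-sized background Grainyhead was 0.673. Against flanks the B box had no match in either set and gave no value. No paired comparison of samples was possible because there is only 1 group. The flanks came from the same summits as the peaks, but the test against them was not paired.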

Other observations

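The following gene counts were looked at after the data had been seen. Among 57 gene families defined by symbol, 5 passed the test, including RpL (36 of 44) and RpS (23 of 35) with more peaks and microRNA genes with fewer (4 of 79, 5.06%, Fisher's exact test, adjusted p = 0.00104). For microRNA genes too the annotated start was taken as the TSS. Of 12 testable genes named as subunits of the V-ATPase proton pump, 7 had a promoter peak (Vha55, Vha100-2, Vha36-1, Vha44, Vha16-5, Vha68-1 and Vha68-2), which did not pass (exact test, adjusted p = 0.0688). Protein-coding genes had a peak in 23.9% of testable cases and the other genes in 12.98% (odds ratio 2.10, Fisher's exact test, adjusted p = 6.265e-19). The other genes were not uniform: ncRNA genes (13.4%, exact test, adjusted p = 1.991e-13), snoRNA genes (12.4%, adjusted p = 0.0193) and tRNA genes (7.48%, adjusted p = 5.717e-06) had fewer, and snRNA genes more, at 50% (adjusted p = 0.0247), though not as a family by symbol (adjusted p = 0.220).

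Some genes held many peaks within their span. The most were in lncRNA:CR44357, with 15 thresholded summits in 239347 bp of X, and in CG1677, which overlaps it, with 13. CHES-1-like, which encodes a Forkhead protein, had 12 in 27048 bp of X (0.444 per kb), and HmgZ was denser, at 0.482 per kb. The genes ush and kirre had 11 each, over 64341 bp and 394149 bp, and Raf and sbb had 9 each. No test of clustering was run on these values.

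In the weighing that follows, the tests of housekeeping genes, of random positions and of the share of genes with a peak were chosen late. The counts and shares that fix their results had been seen by then. They describe the lists and are not tests of a prediction. The coding-sequence pattern was picked after the location results were seen, in place of the lower GC content of peaks, for which tests had been set out and were not run. The design has a single group, so no biological explanation was tested for any of the 3 patterns.

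Ribosomal protein promoters carried peaks with an odds ratio of 12. GC content is unlikely to be the source, since the odds ratio within GC strata was 12.8 (95% interval 7.39 to 22.1), and within strata of the number of nearby TSSs it was 11.7 (6.70 to 20.4). Replicate 3 alone gave 9.84 (5.91 to 16.4), so replicate 1 was not the only carrier. Other housekeeping genes were those of the proteasome, translation factor and respiratory chain lists. They had a peak in 27 of 121 cases, with an odds ratio of 1.005 (0.653 to 1.55). The counts of these lists were known beforehand, so this shows only that they lacked the excess. Open promoters of very high transcription stay open as an explanation, since no expression data or control were analysed here.

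Outside promoters, 8 of 1244 summits (0.643%) were in coding sequence, compared with 23.6% of other relaxed regions. Within GC strata the odds ratio was 0.0877 (95% interval 0.0407 to 0.189), weaker than the unstratified 0.0209, so GC content could account for part of the pattern and not for all of it. Against random positions it was 0.0358 (0.0178 to 0.0717), so the depletion was also present without the relaxed regions as background. The shares behind this value had been seen beforehand. The promoter class held most of the 29 summits in coding sequence, but with promoter status ignored the odds ratio was still 0.0375 (0.0260 to 0.0541), so that class does not account for the pattern.

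The peak at the promoter of CG11398 could be a chance member of the list, since 10.6% of annotated genes (10.1 to 11.0) had one. Extra copies of the locus in the tagged line may also raise reads there. The window held more relaxed regions than 74.6% of random windows, which lies between the bounds set for and against that explanation and leaves it open. In replicate 1 the figure was 67.6% and in replicate 3 it was 92.55%, nearer to the upper bound of 95% but under it. Each replicate had a region at the peak, the strongest of the window, at ranks 2991 and 3726 and so outside the top 2712.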
